A study of Arabidopsis thaliana with 8 samples.

How the data were processed

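RNA was measured in Arabidopsis thaliana seedlings grown in vitro for 3 weeks at 22 °C, as the labels' protocols describe. Stressed plants were moved to 37 °C for 30 h and were sampled either at once (no recovery) or after 2 days back at 22 °C (recovery), and mock plants stayed at 22 °C. The 4 groups (mock and heat, at each of the 2 times) had 2 biological replicates each, 8 Affymetrix arrays in all. Total RNA was column-purified and labelled with biotin by the manufacturer's standard method, per the labels' protocols.

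The authors deposited 1 processed value per probe set and array. GCRMA (background correction by probe sequence, quantile normalization and summary of the probes on the log2 scale) is the tool named in the submitters' processing notes, and its version is not given in the sources used here. The deposited values had lost their decimal point, since 0 of 182480 held one. The point was restored after the first digit, or after the first 2 digits for a value that starts with 1. Of all values 10444 began with 10 to 15, 172036 with 21 to 99 and 0 with 16 to 20, so each value had 1 possible reading on a log2 scale. Restored values ran from 2.18 to 15.23, and the intervals on either side of the join held similar numbers (718 values from 9.9 to 10.0 and 670 from 10.0 to 10.1). The log2 scale of these deposited values is thus a reading of the numbers together with the GCRMA label, and every log2 change rests on it. Because the values were already normalized between arrays, no further scaling was applied, and a change of all transcripts together would not be visible.

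After 64 control probe sets were left out, 22746 of 22810 probe sets were tested. The gene table used here gave 1 gene for 13513 of them, several for 503 and none for 8730. Unlisted probe sets were tested and counted but are unnamed here. Of the probe sets with 1 gene, 13436 matched a RefSeq gene of the TAIR10.1 assembly, used for names, gene classes and organelles only. No coordinates are given because the array's genome build is not given in the sources used here. Coverage was uneven: 14.6% of coding genes with a symbol had a probe set with 1 gene, against 63.1% of those without. Values below log2 2.3 were read as the floor of the array signal. They made up 31.4% of values, and 5742 probe sets lay there on all 8 arrays. A log2 change against a group at the floor on both arrays is a minimum and is given as "at least". For arrays, 2 per group limit the precision, and no read depth applies.

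The tests used limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 8 arrays, which left 4 residual degrees of freedom. Contrasts were tested two-sided with moderated variances, and p was adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. Log2 changes are given ± their standard error from this model (n = 2 arrays per group), and group levels ± SD. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes and again with an estimated correlation, with adjusted p over 20 lists in each comparison. A gene with several probe sets was represented by that with the highest mean. Python 3.11.15 with pandas 2.3.3 read the table, and matplotlib 3.10.9 drew the plots.

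The tests, the alternatives, the rule for named genes and 23 gene lists were set before the data were examined. The rule took the 5 largest rises and 5 largest falls past the threshold in each heat comparison, from probe sets with 1 gene whose heat arrays both lay outside the range of the mock arrays. It added up to 3 members with the smallest p from each list with a called member, and the member with the smallest p that moved against the list. For the other comparisons it took the 3 largest changes each way, and for persistence the 4 largest rises and 4 largest falls. For transposable elements it took the 5 smallest p in each heat comparison. Genes that the rule would always have named had no probe set with 1 gene and are not analysed here.

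Of the 413 genes on those lists 55 had a probe set with 1 gene, and 7 lists had the 3 members that the list test required. The other 16 lists gave only single genes or none. The planned lists of transposable elements and ribosomal proteins were to be built from gene descriptions, which were not used here. RefSeq's pseudogene class (923 probe-set genes) stood in for the former, and a hand-written list of loci for the latter. The full pseudogene class takes in all 8 loci of the ATCOPIA78 family, as well as other pseudogenes. However, 0 of these 8 loci had a probe set with 1 gene, so no probe set could be assigned to the family here. Whether any of the 8730 probe sets without a listed gene, or the 503 with several, reports it was not examined. The pseudogene and ribosomal lists and 11 more, 13 in all, were written after the gene names were seen and before any test. The result of 1 of them is not reported here.

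The procedure was tested on simulated arrays with 200 changed probe sets for each heat comparison. These were drawn only from probe sets with log2 of at least 4 on at least 2 arrays, so the recovered shares do not cover weaker signals. All other probe sets were given equal means in heat and mock. For the comparison without recovery, over 22746 probe sets, 11.9% of changes of 0.5 log2 units, 37.3% of changes of 1 and 66.7% of changes of 2 were recovered, and 11.5% of calls were false. For the comparison after recovery, over 22746 probe sets, the recovered shares were 4.5%, 34.3% and 56.1%, and 12.5% of calls were false. In this single simulation of each comparison the false share was thus above the nominal 5%. The simulation took each probe set's measured residual SD as its true spread, and 3832 of these SDs were under 1e-06. The simulated spreads may thus be more uneven than the true ones, so the false and recovered shares may differ in real data. Over the 13849 probe sets with log2 of at least 4 on at least 2 arrays, 90.9% and 86.4% of changes of 2 log2 units were recovered, without and after recovery, with 1.9% and 2.8% of calls false.

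Alternatives were a replicate block, only the 4 arrays compared, a variance trend, robust variances, another quantile normalization, a shift of each array to a common median, a filter on low signal, a higher floor, a 2-fold limit, a threshold of 0.01, exclusion of probe sets that match several transcripts, other list settings, and each array left out in turn. With an array left out, its group's remaining array was assumed to vary like the other groups.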

Results

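Expression was measured on 8 arrays of 3-week-old seedlings, 2 each from mock and heat-stressed plants sampled directly after 30 h at 37 °C, and 2 each from mock and heat-stressed plants sampled 2 days later. The median log2 value of an array ran from 5.04 to 5.11, and 30.8% to 31.8% of its values were at the floor. Replicates correlated at 0.995 to 0.996 across probe sets. The correlation of the mock and heat group means, across probe sets, was 0.899 without recovery and 0.993 after recovery.

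The first comparison asked what 30 h at 37 °C did to transcript levels. Heat shock proteins and their partners were among the genes raised most. AT3G02480, which belongs to the late embryogenesis abundant proteins, went from 2.29 ± 0.08 in mock to 13.26 ± 0.31 in heat (SD, n = 2), a log2 change of 10.97 ± 0.15. The cytosolic small heat shock proteins HSP17.6C-CI (AT1G53540) and HSP17.6B-CI (AT2G29500) rose by 10.23 ± 0.28 and 9.32 ± 0.37. ROF2 (AT5G48570), a peptidyl-prolyl isomerase, rose by 9.37 ± 0.40. AT2G07722, which lies in the copy of mitochondrial DNA on chromosome 2, was at the floor in mock and rose by at least 9.30 ± 0.61. The deepest falls were those of AT3G15450 (-8.60 ± 0.18), AT3G15630 (-7.34 ± 0.23), AT3G05730 (-7.29 ± 1.05) and AT5G48490 (-7.19 ± 0.18), while AT1G66100, a thionin, fell to the floor (at least -7.99 ± 0.16). Adjusted p for these 10 genes was between 2.00e-05 and 0.0063. The call of AT3G05730 ended when only the 4 arrays compared were fitted (adjusted p = 0.067, with 0.000104 to 0.067 over its alternatives).

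Of the 11 small heat shock proteins measured, which keep other proteins from aggregating, 9 rose and 1 fell, over all probe sets tested and likewise adjusted over the list alone. Their median log2 change was 6.41. HSP26.5 rose by 6.94 ± 0.07, HSP22.0, located in the endoplasmic reticulum, by at least 7.43 ± 0.13, and the mitochondrial HSP23.5-M by at least 8.06 ± 0.08. HSP15.4 fell by 3.23 (SE 0.13), and HSP21.7 had a log2 change of -0.36. All 6 large chaperones and co-chaperones measured rose, also when adjusted over the list alone, with a median of 4.42. Among them were HOP3, which links the HSP70 and HSP90 chaperones (7.71 ± 0.14), HSA32 (5.14 ± 0.11) and BOB1 (2.57 ± 0.11). Camera gave both lists an adjusted p of 2.39e-05, and an adjusted p of 0.274 with an estimated correlation. Of the 4 genes of the endoplasmic reticulum stress response, 3 rose, with the same 3 adjusted over the list alone. ERDJ3B rose by 1.59 ± 0.09, the transcription factor BZIP28 by 1.80 ± 0.12 and CRT1B by 0.69 ± 0.11, while BZIP60 had a change of -0.11 ± 0.15. As a set they missed the threshold (adjusted p = 0.0785).

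**Figure D1:**
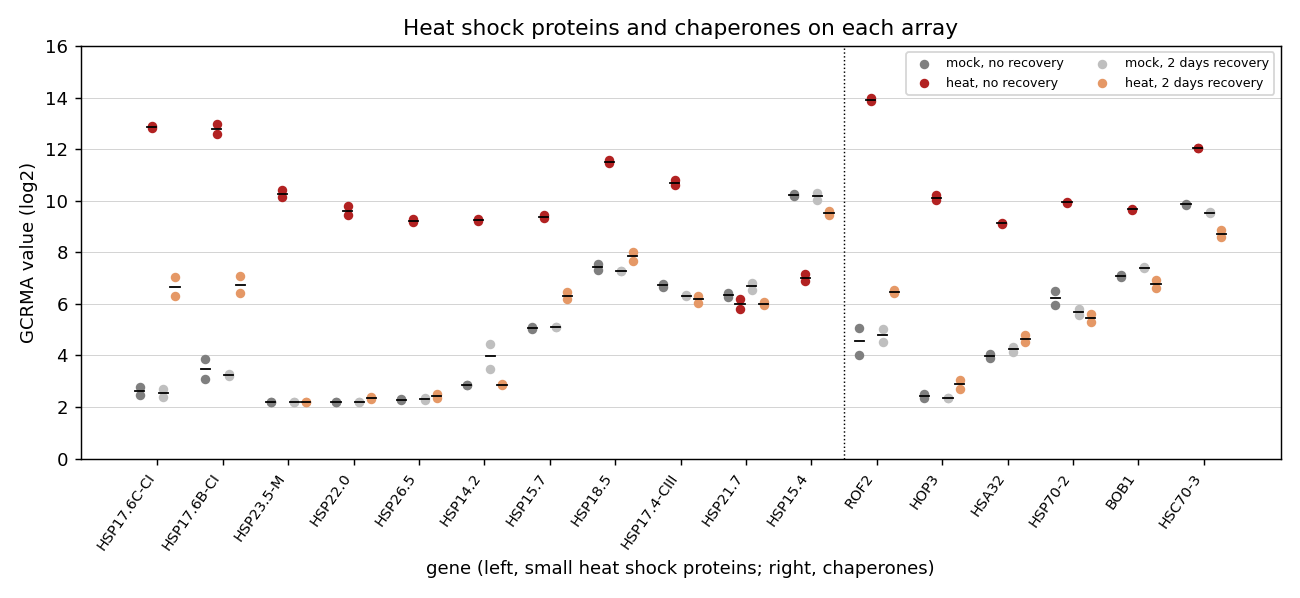
GCRMA values (log2) of the measured small heat shock proteins (left of the dotted line) and chaperones (right) on each of the 8 arrays. Points are arrays and short bars group means; HSP17.6C-CI stood at 12.85 after heat and 6.66 after recovery, against 2.62 and 2.54 in the mock groups.

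Signal on probe sets of mitochondrial genes was mostly higher, and transcripts of the copy of mitochondrial DNA on chromosome 2 cannot be told apart from it. Of 16 mitochondrion-encoded genes 14 rose and 1 fell, with a median of 6.55 (camera adjusted p = 6.40e-08, and adjusted p = 0.274 with an estimated correlation). nad7, a subunit of respiratory complex I, rose by 4.44 ± 0.05, ccb206, for cytochrome c maturation, by 4.99 ± 0.06, and matR, a maturase, by at least 6.07 ± 0.08. ccb382 fell by 1.04 (SE 0.10). A control probe set for the 25S ribosomal RNA, another transcript without a messenger's poly(A) tail, also stood higher on the heat arrays, at 13.49 ± 0.11 against 11.58 ± 0.21 (SD, n = 2). Of 69 plastid-encoded genes 22 fell and 4 rose, with a median of -0.43 (camera adjusted p = 0.0019, and adjusted p = 0.697 with an estimated correlation). petB and petN, of the cytochrome b6f complex, rose by 0.52 ± 0.04 and 1.95 ± 0.21, whereas petA of the same complex fell by 1.2 (SE 0.13). Without mock no-recovery replicate 1 the adjusted p of the plastid list was 0.0538.

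Nuclear genes for photosynthesis fell. Of 7 measured, 6 fell and 1 rose, with the same counts adjusted over the list alone and a median of -1.63 (camera adjusted p = 0.0020, and adjusted p = 0.274 with an estimated correlation). The antenna protein LHCB4.2 fell by 3.64 (SE 0.11), PSBY by 1.76 (SE 0.06) and PSAE-1 by 1.68 (SE 0.06), and the isoform LHCB4.3 rose by 2.09 ± 0.23. Of 94 cytosolic ribosomal proteins 58 rose and 4 fell, with a median of 0.61 (camera adjusted p = 2.67e-08, and adjusted p = 0.664 with an estimated correlation). RPL31B rose by 1.80 ± 0.08 and RPS9C by 3.46 ± 0.21, and RPS7B fell by 0.91 (SE 0.01). The 5 core histones measured were all H2B genes, of which 4 fell, also when adjusted over the list alone (median -0.71, camera adjusted p = 0.0127, and adjusted p = 0.279 with an estimated correlation). HTB3 fell by 3.82 (SE 0.13), HTB11 by 2.33 (SE 0.08) and HTB1 by 0.71 (SE 0.11). Over probe sets with log2 of at least 4 on at least 2 arrays the histone list had an adjusted p of 0.0523.

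Of 3 genes of the abscisic acid and dehydration list, COR15A rose by 5.68 ± 0.53 and COR47 by 1.69 ± 0.22, while COR15B changed by 0.80 ± 0.39. These 2 rises were also the count adjusted over the list alone, and the list had an adjusted p of 0.0946. Of 3 root markers PYK10, a root and seedling beta-glucosidase, fell by 2.71 (SE 0.27). EXPA7 and EXPA18 were at the floor in every group, so their change could not be measured, and the list's adjusted p of 0.585 rests on PYK10 as the 1 gene with a signal. Lists with 1 or 2 measured genes gave single values. APL3, a subunit of the starch enzyme ADP-glucose pyrophosphorylase, rose by 2.15 ± 0.32, and LIG4, a DNA ligase, by 0.71 ± 0.10. EXPA8, an expansin, fell by 4.56 (SE 0.41), SAG101, a defence regulator, by 2.03 (SE 0.15) and the clock gene GI by 0.85 (SE 0.14). The defensin PDF1.2b fell by 4.11 (SE 1.13) and the auxin gene IAA29 fell to the floor (at least -0.92 ± 0.23), but both calls ended under several alternatives (adjusted p up to 0.179 for PDF1.2b and up to 1.00 for IAA29, including with either mock no-recovery replicate left out). Not called were DME, a DNA demethylase (0.29 ± 0.10), the histone chaperones ASF1A (0.16 ± 0.12) and ASF1B (-0.41 ± 0.25), the replication gene MCM7 (0.27 ± 0.18), the kinase AUR1 (-1.85 ± 0.59), ZAT10 (0.36 ± 0.56), and PDF1.2a (-2.98 ± 1.15). Of these, AUR1 and PDF1.2a were called lower over probe sets with log2 of at least 4 on at least 2 arrays. The flavonoid genes DFR and UF3GT were at the floor in both groups, so their change could not be measured.

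In total 9334 of 22746 probe sets (41.0%) were called, 4825 higher and 4509 lower, and 2883 and 2855 of them by at least 2-fold. Of these calls 5071 had 1 gene, 353 rises had a mock group at the floor and 108 falls a heat group at the floor. GAPDH control probe sets at the 3' and 5' ends, a measure of RNA degradation, differed by 3.19 ± 0.04 in mock and 2.95 ± 0.22 in heat (SD, n = 2). Leaving out single arrays gave 7578 to 8875 calls. In the simulation of this comparison 11.5% of the calls were false. It changed 200 probe sets, far fewer than the 9334 called here, so that share does not carry over to these calls. Their own false share was not measured, and calls near the threshold may be less secure than the nominal 5%.

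The second comparison asked what was left 2 days after the stress. Few genes passed the threshold, in a fit that recovered 34.3% of simulated changes of 1 log2 unit. AT1G48720, on a probe set that matches several transcripts, had the largest rise among named genes, at 7.50 ± 0.21 against a mock group at the floor (SD, n = 2), at least 5.32 ± 0.27. HSP17.6C-CI was still raised by 4.12 ± 0.28. AT3G15720 was higher by 3.74 ± 0.16, AT5G11410 by 1.58 ± 0.10 and AT3G28310, at the floor in mock, by at least 1.44 ± 0.09. Lower were the expansin-like EXLB1 (-1.96 ± 0.15), AT1G21320 (-1.64 ± 0.12), AT3G62960 (-1.44 ± 0.09), AT5G50010 (-0.89 ± 0.01) and UGT78D1, a flavonol glycosyltransferase (-0.85 ± 0.05). Adjusted p ran from 0.000526 to 0.0456. With only the 4 arrays compared, all of these calls but that of AT5G11410 ended, and adjusted p over the alternatives reached 0.106 for AT1G48720 and 0.240 for AT1G53540 (HSP17.6C-CI). For AT5G11410 the mock recovery arrays were identical at 3.18, and the heat recovery arrays stood at 4.76 and 4.75. The fit of only these 4 arrays thus had a spread near 0 for it, against SDs of 0.18 and 0.11 in the no-recovery groups. AT3G28310, AT3G62960 and AT5G50010 stayed below log2 4 on all arrays, and their differences vanished when values under 4 were set to 4. AT5G50010 read the same 2.42 on both heat arrays of each time and on 1 mock no-recovery array. Its SE of 0.01 may thus understate its spread. For AT1G21320, AT3G62960 and AT5G50010 the mock plants of that day stood at 4.57, 3.72 and 3.31, against 2.86, 2.45 and 2.41 in mock plants 2 days earlier. The recovered plants, at 2.93, 2.28 and 2.42, were near the earlier mock level, so these differences lay mostly in the mock change. EXLB1 and UGT78D1, at 3.56 and 6.89 in recovered plants, were below the earlier mock levels of 4.66 and 7.90 too.

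Of the 11 small heat shock proteins 1 remained called, against 4 higher and 3 lower adjusted over the list alone. HSP15.7 differed by 1.22 ± 0.12 (adjusted p = 0.0646), HSP17.6B-CI by 3.51 ± 0.37 (adjusted p = 0.0719) and HSP15.4 by -0.65 ± 0.13 (adjusted p = 0.174). As a set they had a median of 0.13 (adjusted p = 0.147). None of the 6 chaperones was called, with 3 higher and 2 lower adjusted over the list alone (median 0.09, adjusted p = 0.990 for the set). Over probe sets with log2 of at least 4 on at least 2 arrays, 3 small heat shock proteins were called higher, HSP15.7 (adjusted p = 0.0091) and HSP17.6B-CI (adjusted p = 0.0034) among them, as was 1 chaperone, ROF2 (adjusted p = 0.0351), while 2 chaperones were called lower. The photosynthesis list had a median of -0.03 (adjusted p = 0.862). The root markers had an adjusted p of 0.862, again with 1 gene off the floor.

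Camera called 7 lists after recovery, though RPS7B was the only member of these lists that passed singly, and its call was lost over the probe sets with log2 of at least 4 on at least 2 arrays (adjusted p = 0.398). Over those probe sets 5 mitochondrion-encoded and 2 abscisic acid and dehydration genes were called higher, and 1 endoplasmic reticulum stress gene and 1 plastid-encoded gene lower. Mitochondrion-encoded genes were higher (median 0.52, adjusted p = 1.37e-06, and adjusted p = 0.356 with an estimated correlation), as were the 3 abscisic acid and dehydration genes (median 1.58, adjusted p = 0.0031, and adjusted p = 0.356 with an estimated correlation), all 3 of them past the threshold adjusted over the list alone. Lower were cytosolic ribosomal proteins (median -0.20, adjusted p = 1.69e-10, and adjusted p = 0.491 with an estimated correlation), with RPS7B at -0.18 ± 0.01, RPS13A at -0.32 ± 0.04, RPL26A at -0.42 ± 0.06 and RPL35D at 0.15 ± 0.18. The mock plants of that day stood higher for this list than those 2 days earlier, by a median of 0.25. The endoplasmic reticulum stress list (median -0.47, adjusted p = 0.0031) and the histones (median -0.38, adjusted p = 0.0117) were lower as well, with an adjusted p of 0.356 for each with an estimated correlation, and with 2 and 3 members lower adjusted over the list alone. From the earlier to the later mock plants, the median change was 0.10 for endoplasmic reticulum stress genes and 0.16 for histones. For abscisic acid and dehydration genes it was -0.37. Camera called none of these mock changes (adjusted p = 0.211, 0.118 and 0.533). Part of these recovery differences may thus lie in the mock plants. Without mock recovery replicate 1 the histone list had an adjusted p of 0.149. Autophagy genes were higher (median 0.32, adjusted p = 0.0063, and adjusted p = 0.491 with an estimated correlation), but without mock recovery replicate 2 or heat recovery replicate 2 their adjusted p was 0.146 and 0.153. Plastid-encoded genes were lower (median -0.08, adjusted p = 0.0495, and adjusted p = 0.908 with an estimated correlation). That call ended under several alternatives, and without heat recovery replicate 2 the median was 0.01 (adjusted p = 0.962), and the mock plants of that day stood higher than those 2 days earlier by a median of 0.08.

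**Figure D2:**
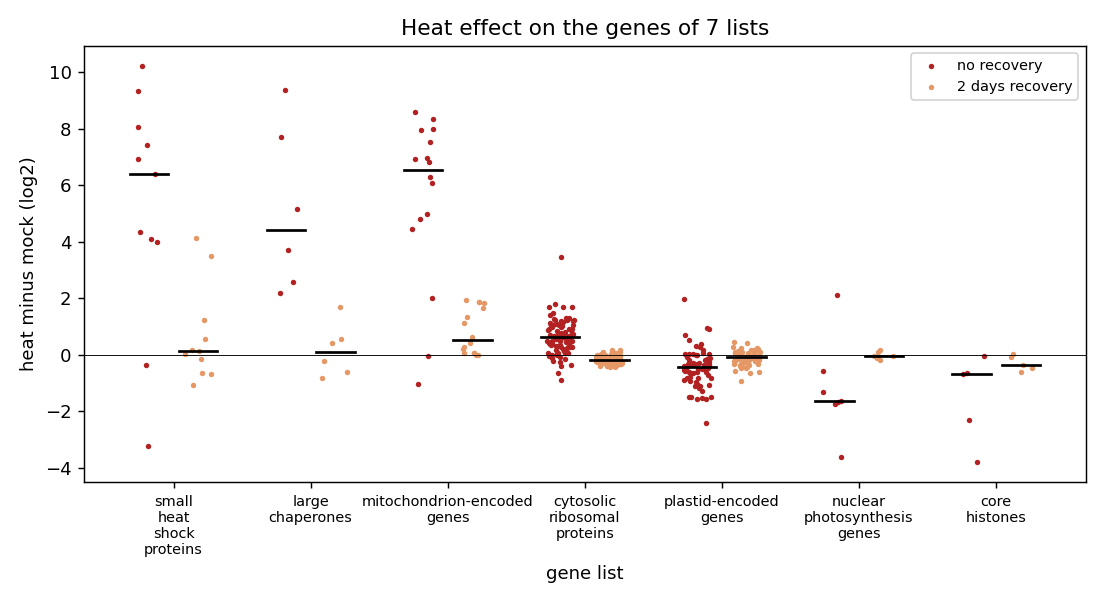
Log2 change, heat minus mock, of each measured gene in 7 lists, without recovery (dark) and after 2 days of recovery (light), with the list median as a bar. The median of the mitochondrion-encoded genes went from 6.55 to 0.52 and that of the small heat shock proteins from 6.41 to 0.13.

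In total 54 probe sets were called after recovery, 30 higher and 24 lower, 12 and 10 of them by at least 2-fold, and 2878 had an unadjusted p under 0.05. Of the 54, 25 had 1 gene. This count depended on the setting: 582 were called over the 13849 probe sets with log2 of at least 4 on at least 2 arrays (300 higher, 282 lower), of which 27 were among the 54, and 1 with only the 4 arrays compared. Leaving out either mock no-recovery array gave 15 calls, either heat no-recovery array 16, mock recovery replicates 1 and 2 244 and 201, and heat recovery replicates 1 and 2 431 and 392. The direction moved with the group that lost an array: 44 higher and 200 lower without mock recovery replicate 1, and 52 and 149 without replicate 2, against 333 and 98 without heat recovery replicate 1, and 321 and 71 without replicate 2.

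Over the probe sets with log2 of at least 4 on at least 2 arrays, more named genes differed after recovery. These genes, from the 10 largest changes each way, were chosen after their values were seen. AMY1, an alpha-amylase, was higher by 4.63 ± 0.75 (adjusted p = 0.0215), COR27, a cold-regulated gene, by 3.63 ± 0.38 (adjusted p = 0.0069) and the defensin PDF1.4 by 3.48 ± 0.50 (adjusted p = 0.0154). Lower were AT4G10270 (-2.76 ± 0.57, adjusted p = 0.0443), AT2G43140 (-2.61 ± 0.33, adjusted p = 0.0112), the transporter OCT1 (-2.57 ± 0.37, adjusted p = 0.0154) and AT2G47880 (-2.38 ± 0.33, adjusted p = 0.0145). Over all probe sets none of these 7 was called (adjusted p from 0.0895 to 0.240). COR27 stood at 8.73 after recovery from heat and at 5.10 ± 0.91 in the mock plants of that day, against 7.41 ± 0.12 in mock plants 2 days earlier (SD, n = 2). In mock plants of that day AT4G10270 and AT2G43140 both stood at 6.95, against 5.25 and 4.73 in the earlier mock plants. Recovered plants stood at 4.19 and 4.34, so much of these 2 differences lay in the mock change. By contrast, OCT1 and AT2G47880 stood at 2.78 and 5.55 after recovery from heat, against 5.78 and 7.25 in the earlier mock plants.

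The third question was whether the heat effect itself differed between the 2 times, tested as an interaction. It was lower after recovery for AT3G02480 (-10.13 ± 0.22), HSP23.5-M (-8.04 ± 0.12) and LEA4-5, a late embryogenesis abundant protein (-8.04 ± 0.35). The first of these values had 1 group at the floor, and the others had 3 of 4 there and so no measurable heat effect after recovery, which leaves the size of these differences open. It was higher by 8.91 ± 0.25 for AT3G15450, by 8.0 ± 0.33 for AT3G15630 and by 7.27 ± 0.51 for AT1G23390, all of which fell in heat before recovery. These log2 differences had adjusted p between 5.63e-05 and 0.0014. The difference was called for 7350 probe sets, 3504 of them positive and 3846 negative. By list, the median difference was -5.81 for small heat shock proteins, -4.33 for chaperones, -5.41 for mitochondrion-encoded genes, -1.65 for endoplasmic reticulum stress genes, 1.59 for photosynthesis genes and -0.82 for ribosomal proteins. Camera called these 6 lists (adjusted p from 3.68e-11 to 0.0162), and with an estimated correlation the adjusted p was 0.592 for ribosomal proteins and 0.217 for each of the others.

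Few genes were called in both heat comparisons, which share no array but share each probe set's variance estimate. HSP17.6C-CI, AT1G48720, AT4G03030 and AT5G14680 were higher at both times, the last 2 by 0.62 ± 0.04 and 0.30 ± 0.02 after recovery, and AT1G21320 and RPS7B were lower at both. After recovery the calls of AT5G14680 and RPS7B were lost over probe sets with log2 of at least 4 on at least 2 arrays (adjusted p = 0.172 and 0.398). The later call of AT1G21320 lay in the mock plants, at 4.57 against 2.86 earlier, with recovered plants at 2.93. It is thus no sign of a lasting fall. EXLB1 and UGT78D1 went the opposite way, at 4.18 ± 0.15 and 1.40 ± 0.05 without recovery. In all, 15 probe sets were higher at both times, against 6.36 for independent lists of these sizes, and 6 were lower at both, against 4.76. The shared variance favours the same probe sets in both lists, so an excess over these values is not by itself evidence of persistence. Another 9 changed in opposite directions, against 11.0, and 24 were called after recovery alone, which does not test a difference. Over probe sets with log2 of at least 4 on at least 2 arrays, 123 were higher at both times (105.5 for independent lists), 138 lower at both (99.3) and 218 opposite (204.9). The 2883 probe sets raised at least 2-fold by heat had a median log2 change of 1.67 at that time and 0.00 after recovery, and the 2855 lowered as far had -1.78 and 0.00. After recovery 103 and 99 of them still differed at least 2-fold the same way, and 29 and 69 differed as far the opposite way. Across probe sets, which are not independent replicates, the changes at the 2 times correlated at 0.12 (Pearson) and 0.02 (Spearman). With single arrays left out, the 21 calls shared in 1 direction became 4 without either heat no-recovery array, 6 and 5 without mock no-recovery replicates 1 and 2, 35 without mock recovery replicate 2, and 87 and 62 without heat recovery replicates 1 and 2.

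**Figure D3:**
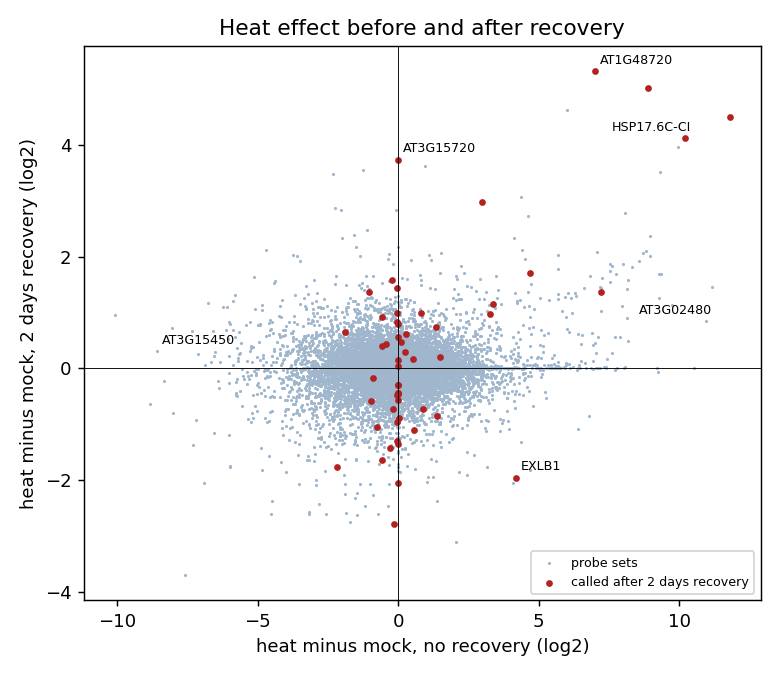
Log2 change, heat minus mock, of each probe set without recovery (horizontal) and after 2 days of recovery (vertical), with the 54 probe sets called after recovery in red and 6 genes named. Most probe sets lie near 0 on the vertical axis, and AT1G48720 stands at 7.0 and 5.32.

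Mock plants of the 2 times were compared to measure what 2 more days of growth changed without heat. AT5G50010 was higher on the later day by 0.90 ± 0.01, AT4G35070 by 0.50 ± 0.02 and AT3G06220, at the floor on the first day, by at least 0.44 ± 0.01. AT1G57630 fell to the floor (at least -0.93 ± 0.03), PUB23, a ubiquitin ligase, changed by -0.88 ± 0.03 and AT4G19520 by -0.53 ± 0.02. All of these but AT4G19520 stayed below log2 4 on every array. The SE of AT5G50010 rests on the same repeated values as above and may understate its spread. Ribosomal proteins were higher as a set (median 0.25, camera adjusted p = 6.31e-22, and adjusted p = 0.663 with an estimated correlation), and so were plastid-encoded genes (median 0.08, adjusted p = 0.0265, and adjusted p = 0.772 with an estimated correlation). In total 18 probe sets were called (1964 at an unadjusted p under 0.05), 10 higher and 8 lower, of which 2 were among the 21 called over probe sets with log2 of at least 4 on at least 2 arrays. The count was 361 and 202 without mock no-recovery replicates 1 and 2, 215 and 169 without mock recovery replicates 1 and 2, 4 without either heat no-recovery array and 6 without either heat recovery array. Here too the direction moved with the group that lost an array, with 48 higher and 313 lower without mock no-recovery replicate 1, and 191 and 24 without mock recovery replicate 1.

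Heat-stressed plants of the 2 times differed almost as widely as heat and mock did before recovery. AT3G15450 rose over the recovery by 9.01 ± 0.18, AT3G15630 by 7.73 ± 0.23 and AT1G23390 by 6.89 ± 0.36, and AT3G02480 changed by -10.24 ± 0.15. HSP23.5-M and LEA4-5 returned to the floor (at least -8.07 ± 0.08 and -8.04 ± 0.25). Of the small heat shock proteins 9 fell and 1 rose (median -6.03, camera adjusted p = 1.49e-05, and adjusted p = 0.235 with an estimated correlation). All 6 chaperones fell (median -4.47, with the same adjusted p and the same value with an estimated correlation). In total 9081 probe sets were called, 4336 higher and 4745 lower after recovery, against 18 between the mock groups.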

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

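All tests of explanations in this part were chosen after the result was seen.

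The heat effect differed between the 2 times, by the test of the difference itself, for 7350 probe sets. The named genes with the largest differences were AT3G15450 (8.91), AT3G15630 (8.0) and AT1G23390 (7.27) on 1 side, and AT3G02480 (-10.13), HSP23.5-M (-8.04) and LEA4-5 (-8.04) on the other. The size of these last 3 is not fixed, since AT3G02480 had 1 group at the floor and the other 2 had 3 of 4 there. Of the lists, small heat shock proteins had a median difference of -5.81, chaperones of -4.33, endoplasmic reticulum stress genes of -1.65, photosynthesis genes of 1.59, mitochondrion-encoded genes of -5.41 and ribosomal proteins of -0.82. A control probe set that no comparison used, for 25S ribosomal RNA, was higher by 1.91 on the heat arrays without recovery and by 0.16 after recovery.

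The signal of mitochondrion-encoded genes rose by a median of 6.55 log2 units without recovery, together with that 25S signal. More degraded RNA in heat is argued against by the 3' minus 5' control differences, which were no higher in heat than in mock (-0.24 for GAPDH, -0.14 for ubiquitin). RNA of both organelles without poly(A) tails, carried into the labelling, is argued against as the whole cause by the plastid-encoded genes, whose 95th percentile was 0.63, although the 25S rise goes with it and a carry-over of mitochondrial RNA alone stays open. Transcripts of the mitochondrial copy on chromosome 2 cannot be told apart from those of the mitochondrion, because 23 of the 27 coding probe sets named for that stretch rose too and no table says which mitochondrial genes lack a copy there. A response of mitochondrial transcript levels to heat, which the design names, stays open and untested.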

How the results depend on the processing

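The crossed replicate block was chosen after seeing the data, as were the genes named with the filter on low signal; the other alternatives were planned. Calls without recovery stayed within 1.5 times of 9334, except 5738 at 2-fold or more. For the difference of effects, 4124 of 7350 were called at 0.01, and for heat over time 5502 of 9081 at 2-fold or more. After recovery, the count of 54 became 201 with the median shift (135 higher and 66 lower, against 30 and 24), 582 with the filter on low signal, 18 with values under 4 set to 4, 22 at 2-fold or more, 6 at 0.01 and 1 with only the 4 arrays compared. For mock plants over time, 18 calls became 10 with robust variances, 8 with values under 4 set to 4, 4 at 2-fold or more, 1 at 0.01 and 0 with only the 4 arrays compared (limma, the 1 tool run, with 2162 at an unadjusted p under 0.05), and the median shift turned 10 higher and 8 lower into 12 and 6. The 21 calls shared by both heat comparisons became 12 with robust variances, 81 with the median shift, 261 with the filter on low signal, 5 with values under 4 set to 4, 9 at 2-fold or more and 1 at 0.01. Stricter thresholds lower a count by construction; elsewhere the cause was not tested, apart from the filter. Leaving out single arrays gave 15 to 431 calls after recovery, 4 to 361 for mock over time and 4 to 87 shared calls, 7578 to 8875 without recovery, 5610 to 6666 for the difference and 7818 to 8264 for heat over time. Called lists fell from 7 to 0 with an estimated correlation, without and after recovery (3 and 2 at an unadjusted p under 0.05); single arrays left out gave 6 to 8 and 5 to 7. No called gene or list turned round, though the plastid list's median after recovery was 0.01 in place of -0.08 without heat recovery replicate 2, its call lost. Of 1861 values of named genes without recovery, 25 lost a call and 2 gained one; of 789 after recovery, 115 lost one and 36 gained one. The scalings moved the median of all probe sets by at most 0.04. Signal over background limits the 5742 probe sets at the floor on all arrays.

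The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at 0.00, 0.04, -0.02, 0.01, 0.15 and -0.13 over the 6 pairs of groups. With the numbers as a replicate block, 8705 probe sets were called without recovery, 18 after recovery, 6545 for the difference, 9 for mock over time, 8486 for heat over time and 6 in both heat comparisons. With the numbers of the heat recovery arrays exchanged, 14 were called after recovery and 6 in both comparisons.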

Other observations

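The 13 lists written after the gene names were seen, and the test of AT1G48720 against comparable probe sets and the test of the number of adjusted probe sets, were chosen after seeing the data or the result; the test of the variance prior was chosen before its result.

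Gene families for metabolism, cell walls and transport were mixed in direction after heat, and none passed the threshold as a set. Members at the floor on all arrays weaken these set tests. Only 12 of 20 beta-glucosidases, 15 of 27 wall proteins and 17 of 29 carboxypeptidase-like proteins lay off it. Their medians were -0.71, 0.50 and -0.16, against 0 for each full list. Of 14 SWEET sugar transporters 3 rose, SWEET1 by 3.02 ± 0.05 and SWEET4 by 4.29 ± 0.19 among them, and 2 fell, SWEET16 by 1.94 (adjusted p = 0.805 for the set). Of 47 UDP-glycosyltransferases, which attach sugars to small molecules, 12 rose and 8 fell (adjusted p = 0.652); UGT73C1 rose by at least 5.76 ± 0.10 and UGT76C2 fell by 2.76. Of 14 glutathione transferases 4 rose and 4 fell (adjusted p = 0.805), with GSTU20 at -2.64 ± 0.19, GSTU18 at -1.22 ± 0.07 and GSTU16 at 0.80 ± 0.07. Among 27 xyloglucan and expansin wall proteins 5 rose and 3 fell (adjusted p = 0.646), XTH16 by 2.02. Trichome birefringence-like proteins, which acetylate wall polymers, gave 3 rises and 6 falls of 22 (adjusted p = 0.235, and 0.697 with an estimated correlation). Their median was -0.05, and -0.20 without mock no-recovery replicate 2. Among them were TBL26 at 4.45 ± 0.17, TBL23 at -0.92 ± 0.06 and TBL45 at -5.77 ± 0.16. Beta-glucosidases (2 rose and 4 fell of 20, adjusted p = 0.646), with BGLU44 at -2.70 ± 0.16, BGLU33 at -2.85 ± 0.18 and BGLU25 at 1.68 ± 0.14, and serine carboxypeptidase-like proteins (3 and 5 of 29, adjusted p = 0.519), with SCPL42 at -1.81 ± 0.11, SCPL27 at -1.79 ± 0.13 and SCPL48 at 1.03 ± 0.07, were mixed as well. Of 10 autophagy genes 5 rose and 2 fell (adjusted p = 0.329), the ubiquitin-like ATG8D by 1.36 ± 0.07, while ATG8E and ATG8F changed by -3.18 ± 0.14 and -1.82 ± 0.09.

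After recovery 2 members of these families were called, UGT78D1 and EXLB1, both lower. UGT85A5 at 1.70 ± 0.17, UGT76C2 at 1.07 ± 0.12, EXPA15 at -0.99 ± 0.12, XTH16 at -0.48 ± 0.12 and EXLA1 at 2.06 ± 0.56 missed the threshold, though all of these but XTH16 were called with the filter on low signal (adjusted p = 0.0056, 0.0122, 0.0145 and 0.0472). With that filter 5 UDP-glycosyltransferases were called higher and 1 lower, and 1 wall protein higher and 2 lower. It also called 3 carboxypeptidase-like proteins higher, and 1 beta-glucosidase and 1 SWEET transporter lower. As sets, UDP-glycosyltransferases had an adjusted p of 0.122 after recovery, 0.0207 upward with the filter on low signal and 0.491 with an estimated correlation. The adjusted p was 0.388 for wall proteins, 0.147 for SWEET transporters and 0.432 for beta-glucosidases. It was 0.862 for glutathione transferases, birefringence-like and carboxypeptidase-like proteins.

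The annotated pseudogenes, the class that holds transposable elements here, gave 21 rises and 5 falls of 923 without recovery, and 10 and 2 adjusted over the list alone. Only 128 of them were above the floor on any array, so the adjusted p of 0.989 for the set says little of the class. The filter on low signal keeps a member at the floor in mock only if heat raised it, so its adjusted p of 0.027 upward over the 24 members kept is partly built in and is no evidence of a shift. AT4G05640 rose by at least 5.51 ± 0.11, AT1G35050 by at least 2.75 ± 0.04 and CYTOSLEEPER by at least 2.47 ± 0.04, and AT4G16870 fell to the floor (at least -5.39 ± 0.06) and AT1G35612 changed by -3.96 ± 0.09. After recovery none was called (adjusted p = 0.624 for the set, and 0.000216 upward with the median shift, the setting that moved all probe sets by 0.04). The smallest p were those of AT1G35612 at 0.40 ± 0.09, AT1G32590 (at the floor on all arrays), AT4G04130 at -0.18 ± 0.06, AT4G08110 at 0.40 ± 0.13 and AT5G34820 at 0.28 ± 0.12.

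AT1G48720 stayed raised after recovery, by at least 5.32 after a rise of 7.0. A slow decay shared by all transcripts raised as far is argued against by 17 probe sets at the floor in mock, where AT1G48720 lay just above it at 2.42, that rose within 1 log2 unit of it: their median after recovery was 0.01 and their highest value 0.70. It had been named for its large rise after recovery, so that none of these reached its level is no evidence, and the bound on their highest value was set after the values were seen; a wider set of 30 with a mock mean of at most 3, run first, had a highest value of 1.86. Both sets leave out probe sets with a mock mean above 3, which were not compared as a group. Of these, AMY1, at 3.91 in mock, also rose within 1 log2 unit of AT1G48720. It was still higher by 4.63 after recovery, though called only with the filter on low signal. AT2G07777, at 3.17 in mock, rose within the same range and was higher by 0.27 after recovery. AMY1 was itself named for its large change after recovery, and its 2 mock arrays lay far apart. Whether AT1G48720 is alone in staying raised is thus left open. A slow decay of AT1G48720 that not all transcripts share, or signal from another transcript on its probe set, may account for its level, and both were untested.

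The filter on low signal gave 582 calls after recovery against 54. Fewer probe sets to adjust over is argued against as the whole cause, since the same p-values adjusted over the kept probe sets alone gave 41 calls. A candidate explanation is that probe sets at the floor, 3832 of which had a residual SD under 1e-06, pull down the prior degrees of freedom of the variance, 0.43 over all and 3.59 over the kept probe sets. With p-values of the filtered fit adjusted over all probe sets there were 300 calls, where the bound set beforehand, 0.5 times the 582, was only just met. The step from 300 to 582 calls came from the adjustment alone. With the p-values of the filtered fit, the number of probe sets adjusted over thus counted as well. No biological explanation was tested for this pattern.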
